A study of Homo sapiens with 36 samples.

How the data were processed

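The series holds RNA sequencing of 36 libraries in 12 groups of 3: NF, TAF and TCF fibroblasts in monoculture and in co-culture with HCC827 cells, and HCC827 cells in monoculture and co-culture for each of these 3 fibroblast sets. Co-cultures lasted 24 h and were separated with beads against fibroblasts, a step stated only for co-cultures. Each cell type was plated at 1600000 cells in monoculture and at 800000 in co-culture. The effect of that number cannot be told apart from co-culture. Tumour-core tissue was dissociated with another kit than normal and tumour-adjacent tissue. The labels speak of 3 independent biological replicates and of matched specimens, but do not say which donor each replicate came from. Libraries were made with TruSeq stranded mRNA and sequenced paired-end on a NovaSeq. Other cultures that the labels mention were not analysed here.

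The deposited table gives 19551 genes in TPM, made by the authors with Salmon (version printed as 091) on GRCh38 per the submitters' processing notes. The annotation, the summing of transcripts to genes and the gene filter are not given in the sources used here. Column totals lay between 950969 and 977645 TPM. TPM keeps no sequencing depth, so the depth is unknown and no counting intervals or floors are given. The plan fixed before the data were examined assumed counts, and since the table held TPM its written alternative for TPM, limma, was used. Y-linked genes and XIST were left out of every step (42 genes), which left 19509.

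Genes with a mean of at least 1 TPM in 1 group were tested on log2(TPM + 0.5) with limma 3.58.1 (trend and robust settings) in R 4.3.3. Fibroblast comparisons used a fit of 18 libraries, HCC827 comparisons another of 18, and tests beyond both monocultures a fit of 36. A gene was beyond both monocultures when it differed in the same direction from the monoculture of its own cell type and from that of the other cell type, by the larger of both p values. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Genes to name were the 10 with the largest log2 change in each direction among those past the threshold with an absolute log2 change of at least 1 and at least 5 TPM in 1 group, and in co-culture comparisons also beyond both monocultures; the rule was written for CPM and applied to TPM.

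There were 31 gene lists (553 entries, all found, 3 under older symbols), fixed together with that plan. They were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. The share of the other cell type in a fraction was the median over marker genes, at least 20 times higher in the other monoculture, of the level above the own monoculture divided by the difference between both monocultures. Mixtures weighted the mean monocultures of the same set by that share. In subtraction, the share times the other monoculture was removed, values below 0 were set to 0 and the rest rescaled, with the share limited to 0.95. Subtraction can widen the spread, as it did for CDK4 in fibroblast fractions. Calls lost after it therefore do not show that RNA of the other cell type caused them. Unmixing solved each pair of fibroblast and HCC827 fractions with the same number, taken as the same culture, for both cell types. Unmixed values below 0 were also set to 0. Levels were compared between 2 groups by a two-sided exact permutation test.

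Whether replicate numbers paired the libraries was checked by the correlation of residuals between libraries with the same number. All such correlations were above 0.1 in NF, TAF and TCF co-cultures against their monocultures and in the HCC827 NF set, so blocked values are given there. That block was the replicate number within a set. Tests beyond both monocultures instead used a block of replicate numbers shared by all sets and both cell types. In no pair of monoculture groups from different sets were all correlations above 0.1, so the shared block is not a pairing seen in the data. Between fibroblast and HCC827 fractions of the same co-culture set these correlations were above 0.1 in the NF and TAF sets, but as low as 0.0553 in the TCF set. Alternatives were limma without trend, upper-quartile rescaling, no filter, a pseudocount of 0.1, the compared libraries alone, the replicate block, subtraction of the other cell type, all 9 HCC827 monocultures as control, leaving out each library, and, added later, leaving out the co-culture library with the largest share of the other cell type.

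The procedure was tested on simulated data with 50 changed genes per fold. At a fold of 2 it recovered between 28% and 56% of them, at 4 between 76% and 94%, at 8 between 92% and 100% and at 16 between 92% and 100%, depending on the comparison. For tests against the own monoculture, simulated co-cultures held no RNA of the other cell type. For tests beyond both they held a fixed share, and the fold was over the higher monoculture. Noise was independent between libraries, and differences between responses were not simulated. The rates therefore do not give the power in these data.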

Results

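Primary human lung fibroblasts were grown alone or together with HCC827, a human lung adenocarcinoma cell line, and each cell type was sequenced, from co-cultures after separation. The fibroblasts came from normal lung (NF), the tumour edge (TAF, tumour-adjacent fibroblasts) and the tumour core (TCF, tumour core fibroblasts). Each of the 12 groups had 3 replicates, and levels are given in TPM as mean ± SD, log2 changes with their SE. Folds are limma estimates on log2(TPM + 0.5), not ratios of the mean TPM. For genes near 0 TPM in monoculture the added 0.5 makes them smaller than on TPM itself.

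In co-cultured NF, interferon-stimulated genes lay above the level of both cell types grown alone. RSAD2, which encodes the antiviral enzyme viperin, rose from 0.262 ± 0.446 TPM to 182 ± 66.2 TPM (SD, n = 3), against 3.04 ± 0.410 TPM in HCC827 monoculture. Its log2 change was 7.99 ± 0.68 (SE, n = 3; limma adjusted p = 5.19e-06), and it lay above both monocultures with an adjusted p of 3.37e-05. CXCL10, a chemokine that attracts T cells, rose from 0.0632 ± 0.0795 TPM to 102 ± 21.1 TPM, while HCC827 monoculture held 0.156 ± 0.0357 TPM. OASL, an antiviral gene, had the largest change on the scale of log2(TPM + 0.5) among the genes above both monocultures (363-fold, log2 change 8.50 ± 0.57). The RNA-binding IFIT1, IFIT2 and IFIT3, the GTPase MX1, the 2 oligoadenylate synthetases OAS1 and OAS2, and the nucleotide kinase CMPK2 rose between 77.8-fold and 242-fold.

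All 21 measured genes of the fixed interferon-stimulated list rose in NF, with a median log2 change of 6.18 (21 adjusted over the list alone; camera adjusted p = 4.21e-56, adjusted p = 0.00618 with an estimated correlation and 0.0844 with that and the replicate number as a block). Of these, 16 lay above both monocultures. Inflammatory cytokine and chemokine genes rose in part: 6 of 23 passed, 10 adjusted over the list alone, led by CXCL6 (log2 change 5.12 ± 0.91, adjusted p = 0.00372) and CXCL5 (3.83 ± 0.79, adjusted p = 0.0109). CXCL1, CCL2, IL6 and TNFAIP3 were the others, and the list as a whole had a camera adjusted p of 2.31e-08 and an adjusted p of 0.324 with an estimated correlation. Antigen presentation genes TAP1 (2.43 ± 0.32), PSMB9, PSMB8, HLA-F and NLRC5 rose, 5 of 14 in all and 5 adjusted over the list alone (camera adjusted p = 4.36e-07, adjusted p = 0.208 with an estimated correlation). The 4 immune cell markers measured moved up too, with a median log2 change of 0.90 and 0 past limma (2 adjusted over the list alone; camera adjusted p = 0.0299, adjusted p = 0.324 with an estimated correlation), and lay at 0.59 ± 0.29 (SD, n = 3) against the mixture. SOD2, a mitochondrial superoxide dismutase, rose by a log2 change of 2.57 (adjusted p = 5.38e-05) and lay above both monocultures. SRXN1 and TXNRD1, redox genes under NRF2, fell by 0.82 and 0.80 on the log2 scale while ABCC2 of the same list rose, and the list passed camera only with the replicate number as a block (adjusted p = 0.0699 without it, 0.0403 with it, and 0.523 with the block and an estimated correlation).

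The NF fractions also held RNA of the other cell type: 13 of 19 epithelial markers rose (18 adjusted over the list alone; camera adjusted p = 1.24e-22, adjusted p = 0.107 with an estimated correlation), and EPCAM went from 3.66 ± 5.15 TPM to 96.3 ± 99.3 TPM. In all, 452 of 13150 genes passed in NF, 424 higher and 28 lower, and 74 of 13535 lay beyond both monocultures. The replicate numbers paired these libraries, and with that block 1111 genes passed, 750 higher and 361 lower. Beyond both, 78 passed with the block shared by all sets, which is not that pairing. After the estimated HCC827 RNA was subtracted 75 passed, and 167 passed with NF libraries alone. The count was 268 without NF monoculture replicate 1, 216 without NF monoculture replicate 3 and 258 without NF co-culture replicate 3. Beyond both monocultures, 48 genes passed without NF co-culture replicate 2.

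In TAF the same gene family responded. IFIT2 rose from 1.80 ± 0.657 TPM to 298 ± 221 TPM (log2 change 6.79 ± 0.70, n = 3, limma adjusted p = 3.74e-05), against 16.9 ± 0.760 TPM in HCC827 monoculture. IFIT3 rose 51.9-fold, RSAD2 56.9-fold, and the ubiquitin-like ligase gene HERC5 rose 28.1-fold. CXCL10 was listed at 0 in all TAF monocultures and reached 18.4 ± 15.0 TPM in co-culture. All 21 measured interferon-stimulated genes rose (21 adjusted over the list alone) with a median log2 change of 5.37 (camera adjusted p = 2.33e-36, adjusted p = 0.0365 with an estimated correlation and 0.275 with that and the replicate block), 5 of them above both monocultures. ICAM1, CXCL5 and CSF2 rose among 23 inflammatory genes (5 adjusted over the list alone), with a list adjusted p of 8.77e-04 by camera and 0.936 with an estimated correlation. TAP1, PSMB9 and PSMB8 rose, and the antigen presentation list had a camera adjusted p of 0.0892, or 0.0313 with the replicate block and 0.504 with the block and an estimated correlation. ICAM1, CXCL5, CSF2, TAP1, PSMB9 and PSMB8 did not pass as above both monocultures. For them that test does not separate a rise in the fibroblasts from HCC827 RNA. SRXN1 fell by 0.70 on the log2 scale (adjusted p = 0.00322).

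All 19 epithelial markers rose in the TAF fractions (19 adjusted over the list alone; camera adjusted p = 1.33e-29, adjusted p = 0.0441 with an estimated correlation and 0.275 with that and the replicate block), EPCAM from 0.263 ± 0.113 TPM to 136 ± 62.1 TPM. In TAF 816 genes passed, 733 higher and 83 lower, and 7 lay above both monocultures: CMPK2, CXCL10, HERC5, IFIT1, IFIT2, IFIT3 and RSAD2. With the replicate block 2057 passed, 1161 higher and 896 lower (8 above both with the block shared by all sets). After subtraction 34 passed, and with TAF libraries alone 1260, 872 higher and 388 lower. Without TAF monoculture replicate 2 the count was 526, and without TAF co-culture replicate 1 it was 433. The 7 genes above both became 0 without TAF co-culture replicate 1, without HCC827 monoculture (TAF set) replicate 1 or replicate 2, and in a fit of the compared libraries alone, and 15 without TAF co-culture replicate 3.

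In TCF, OASL rose from 0.233 ± 0.202 TPM to 273 ± 109 TPM (log2 change 8.51 ± 0.57, n = 3, limma adjusted p = 1.16e-06), against 35.3 ± 25.5 TPM in HCC827 monoculture. IFIT1 rose 236-fold and IFIT2 rose 194-fold. The chemokine genes CXCL10 and CCL5 rose to 13.5 ± 10.4 TPM and 12.5 ± 4.79 TPM, both above both monocultures (adjusted p = 0.0129 and 0.0274). Of 21 measured interferon-stimulated genes 20 rose (21 adjusted over the list alone), with a median log2 change of 5.72 (camera adjusted p = 2.73e-22, adjusted p = 0.0983 with an estimated correlation) and 7 above both monocultures. CSF2, CXCL5, CXCL1, CXCL6 and ICAM1 rose among 23 inflammatory genes (5 adjusted over the list alone; camera adjusted p = 0.214), and TAP1, PSMB9, PSMB8 and NLRC5 rose among 14 antigen presentation genes (4 adjusted over the list alone; camera adjusted p = 0.260). Of these named genes only TAP1 passed as above both monocultures. For the others that test does not separate a rise in the fibroblasts from HCC827 RNA. CXCL6 lay at 3.21 ± 0.65 (SD, n = 3) against the mixture. SOD2 rose by 2.07 and lay above both monocultures (adjusted p = 0.00717).

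Cell-cycle genes rose in the TCF fractions as well. All 23 mitosis genes (23 adjusted over the list alone) and 19 of 22 S-phase genes (22 adjusted over the list alone) rose, with median log2 changes of 3.37 and 2.11. Their camera adjusted p values were 1.15e-11 and 2.33e-08, and 0.454 and 0.564 with an estimated correlation. Against a mixture of both monocultures at each library's HCC827 share, however, the mitosis genes lay at a log2 ratio of 0.04 ± 0.40 (SD, n = 3) and the S-phase genes at -0.12 ± 0.52. Of 18 position transcription factors of lung mesenchyme 4 fell (4 adjusted over the list alone), with log2 changes of -1.59 for TBX2, -1.98 for FOXF1, -2.23 for TCF21 and -1.30 for TBX5 (list camera adjusted p = 4.03e-04, adjusted p = 0.0983 with an estimated correlation). Against the mixture this list lay at -0.38 ± 0.09 (SD, n = 3). Fibroblast markers moved down as well, with a median log2 change of -0.88 and 2 of 20 past limma (0 adjusted over the list alone; camera adjusted p = 5.89e-05, adjusted p = 0.454 with an estimated correlation), as did contractile genes (camera adjusted p = 0.0117, adjusted p = 0.454 with an estimated correlation) and matrix genes (0.00174 and 0.717). Against the mixture these lists lay at -0.12 ± 0.23, -0.32 ± 0.54 and -0.03 ± 0.24, within their spread of 0. CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 1.14 (adjusted p = 0.0223), but lay at -0.47 ± 0.55 (SD, n = 3) against the mixture, within its spread of 0.

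Of 19 epithelial markers 18 rose in TCF fractions (18 adjusted over the list alone; camera adjusted p = 1.67e-16, adjusted p = 0.175 with an estimated correlation), EPCAM from 0.228 ± 0.136 TPM to 194 ± 47.8 TPM. In TCF 2811 genes passed, 2443 higher and 368 lower. Upper-quartile rescaling moved the median gene by -0.131 and gave 2139 higher and 787 lower. With the replicate block 4790 passed, 3249 higher and 1541 lower, after subtraction 91, with TCF libraries alone 1426, and without TCF monoculture replicate 3 it was 1864. Beyond both monocultures 22 genes passed (21 with the block shared by all sets, 6 with the compared libraries alone). This count became 0 without TCF co-culture replicate 1, TCF co-culture replicate 2 or HCC827 monoculture (TCF set) replicate 1, and 7 without HCC827 monoculture (TCF set) replicate 2.

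The genes beyond both monocultures were shared between fibroblast sets. All 7 TAF genes were among the 74 of NF, where 0.0383 were expected for independent lists, and 21 of the 22 TCF genes were among them, where 0.12 were expected. The 7 TAF genes were also among the TCF genes (0.0114 expected). These lists came from the same fit of 36 libraries with shared estimates of the spread, so they were not independent. The expected numbers are therefore no test of the overlap. Differences in response between fibroblast sets passed limma for 0 genes in each of the 3 pairings. At an unadjusted p under 0.05 there were 102 genes for TAF against NF, 1231 for TCF against NF and 885 for TCF against TAF, and limma without a trend also gave 0 (unadjusted 124, 1187 and 853). Without TCF monoculture replicate 1 the latter pairings gave 352 and 369, and without TAF co-culture replicate 1 the first gave 1.

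**Figure D1:**
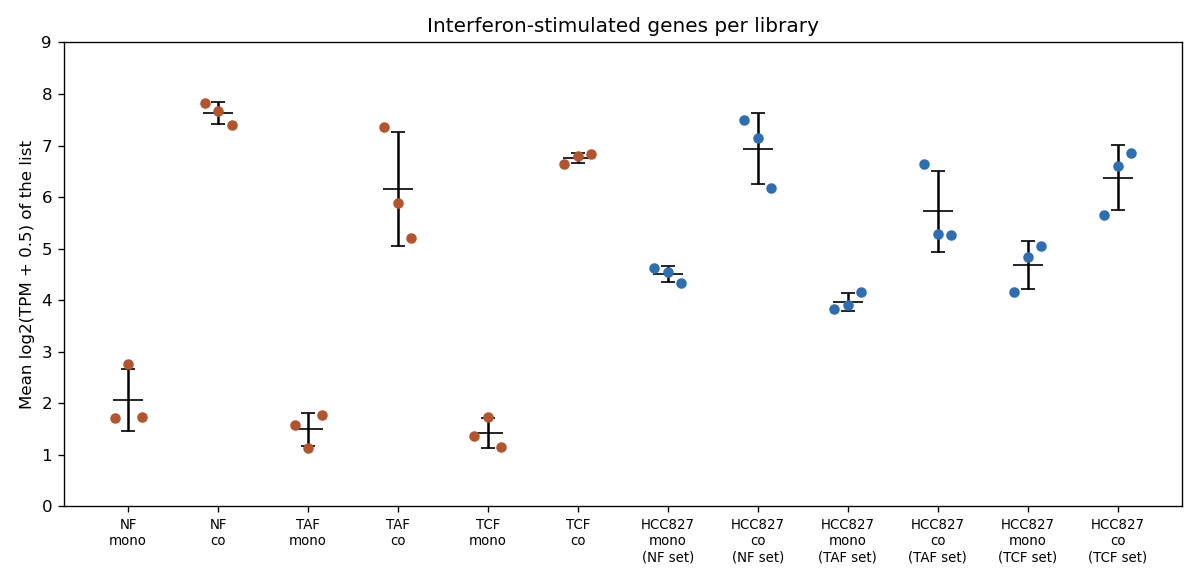
Mean log2(TPM + 0.5) of the interferon-stimulated list per library (vertical axis) in the 12 groups, fibroblast groups in orange and HCC827 groups in blue. Points are libraries, horizontal marks are means and error bars are SD (n = 3); fibroblast co-cultures averaged 7.63 (NF), 6.16 (TAF) and 6.76 (TCF), against 2.06 in NF monocultures and 1.42 in TCF monocultures.

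HCC827 cells of the NF co-cultures showed interferon-stimulated genes too. IFIT1 rose from 35.0 ± 16.1 TPM to 332.5 ± 155 TPM (log2 change 3.19 ± 0.46, n = 3, limma adjusted p = 0.00304) and lay above both monocultures (adjusted p = 0.0186). CMPK2 rose 19.4-fold, RSAD2 15.7-fold, the GTPase MX2 14.4-fold, OAS2 12.6-fold, MX1 8.77-fold and the deubiquitinase USP18 7.68-fold. IRF7, a transcription factor of the interferon response, rose 5.67-fold. Mitochondrially encoded genes, whose level also follows RNA quality, lay lower in these fractions as a list (median log2 change -0.89, 0 of 13 past limma and 0 adjusted over the list alone; camera adjusted p = 0.00703, 0.657 with an estimated correlation and 0.0533 with the replicate block), at -1.04 ± 0.49 (SD, n = 3) against the mixture. Of 21 measured interferon-stimulated genes 17 rose (21 adjusted over the list alone), with a median log2 change of 2.45 (camera adjusted p = 1.1e-26, adjusted p = 0.0618 with an estimated correlation) and 9 above both monocultures. TNFSF10 rose 9.05-fold, but its adjusted p was 0.0671 after the estimated fibroblast RNA was subtracted and 0.240 with the compared libraries alone.

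In the TAF set IFIT1, XAF1 and MX1 rose in HCC827 cells (17 of 21 interferon-stimulated genes adjusted over the list alone), with a list median of 1.98 (camera adjusted p = 6.5e-22, adjusted p = 0.0738 with an estimated correlation). In the TCF set 9 rose (16 adjusted over the list alone), IFIT1 by 2.57 ± 0.46, with a list median of 1.82 (camera adjusted p = 3.46e-14, adjusted p = 0.121 with an estimated correlation). Replication genes fell in HCC827 cells: 4 of 22 S-phase genes in the NF set (8 adjusted over the list alone) and 3 in the TCF set (13 adjusted over the list alone), among them CDC6, which loads the replicative helicase, by 0.55 and 0.68 on the log2 scale. Their camera adjusted p values were 1.33e-06 and 8.24e-13, and 0.178 and 0.042 with an estimated correlation. Against the mixture the S-phase list lay at -0.31 ± 0.08 (SD, n = 3) in the NF set, -0.11 ± 0.05 in the TAF set and -0.26 ± 0.09 in the TCF set. Endoplasmic reticulum stress genes moved up in the TCF set as a list (median log2 change 0.40, camera adjusted p = 2.05e-04, adjusted p = 0.042 with an estimated correlation), with 0 of 15 genes past limma and 6 adjusted over the list alone. Against the mixture that list lay at 0.16 ± 0.09 (SD, n = 3) in the TCF set, 0.12 ± 0.08 in the NF set and 0.21 ± 0.07 in the TAF set.

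Fibroblast markers rose in every HCC827 co-culture fraction: 15, 7 and 18 of 20 in the NF, TAF and TCF sets, and 20 in each adjusted over the list alone. The camera adjusted p values were 3.4e-28, 2.54e-30 and 4.16e-34, and 0.0618, 0.0467 and 0.042 with an estimated correlation. COL1A2, a collagen chain, had log2 changes of 8.45 ± 0.85, 6.72 ± 0.85 and 9.88 ± 0.85. In the NF set 281 of 12702 genes passed, 235 higher and 46 lower. The replicate numbers paired that set, and with the block 762 passed, 433 higher and 329 lower, against 37 after subtraction and 39 with the compared libraries alone. Beyond both monocultures 20 genes passed in the NF set (19 with the block shared by all sets). In the TAF set 46 passed, all higher, and in the TCF set 383 passed, 365 higher and 18 lower. After subtraction both sets gave 0 (395 and 744 at an unadjusted p under 0.05), which does not show that these changes came from fibroblast RNA. For those sets 0 genes lay beyond both monocultures by limma (66 and 107 at an unadjusted p under 0.05).

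The HCC827 counts moved with single libraries. In the NF set the 281 became 116, 77 and 52 without HCC827 monoculture (NF set) replicate 1, 2 and 3, and 25, 126 and 1046 without HCC827 co-culture (NF set) replicate 1, 2 and 3. Of the 10 genes named for that set, 2 passed without HCC827 co-culture (NF set) replicate 1, 7 without HCC827 monoculture (NF set) replicate 3, and at least 9 without any other library. The 20 genes beyond both became 6, 4 and 0 without HCC827 monoculture (NF set) replicate 1, 2 and 3, and 0, 0 and 32 without HCC827 co-culture (NF set) replicate 1, 2 and 3. They became 12 and 13 without NF monoculture replicate 1 and 3. In the TAF set the 46 became 6, 5 and 26 without HCC827 monoculture (TAF set) replicate 1, 2 and 3, and 21, 93 and 5 without HCC827 co-culture (TAF set) replicate 1, 2 and 3. In the TCF set the 383 became 148 and 169 without HCC827 monoculture (TCF set) replicate 1 and 2, and 175 without HCC827 co-culture (TCF set) replicate 3. Beyond both monocultures, 3 passed there without HCC827 co-culture (TCF set) replicate 1.

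HCC827 monocultures did not differ between the 3 sets by limma (0 genes, 485 at an unadjusted p under 0.05; limma without a trend gave 0 and 465), with 1 gene without HCC827 monoculture (TAF set) replicate 2. Differences in the HCC827 response between sets passed for 0 genes (unadjusted 178 for TAF against NF, 246 for TCF against NF and 156 for TCF against TAF; 224, 298 and 185 by limma without a trend, also with 0 past the threshold), with 1 gene for TCF against TAF without HCC827 co-culture (TCF set) replicate 1.

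RNA of the other cell type was estimated from epithelial and fibroblast markers. The HCC827 share of RNA was 21.2% ± 21.1 (SD, n = 3) in NF fractions, 35.9% ± 18.2 in TAF fractions and 42.7% ± 15.8 in TCF fractions. The fibroblast share in HCC827 fractions was 7.46% ± 6.06 in the NF set, 6.77% ± 4.51 in the TAF set and 8.80% ± 0.632 in the TCF set. Without NF co-culture replicate 3 the NF share was 9.22%, and without HCC827 co-culture (NF set) replicate 2 that set's share was 4.94%. Median epithelial marker levels were 31.9 TPM in NF co-culture against 1.23 TPM in monoculture, 47.1 against 0.315 TPM in TAF and 72.6 against 0.461 TPM in TCF. Each gave p = 0.1 in a two-sided exact permutation test, the smallest p that 3 against 3 allows.

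**Figure D2:**
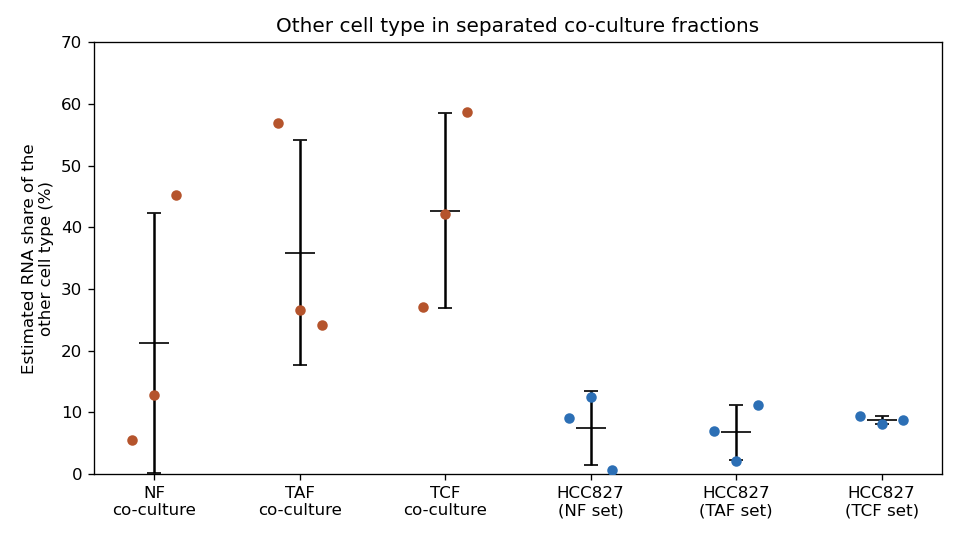
Estimated percentage of RNA from the other cell type (vertical axis) in each separated co-culture fraction. Points are libraries, horizontal marks are means and error bars are SD (n = 3); fibroblast fractions averaged between 21.2% and 42.7% HCC827 RNA, HCC827 fractions between 6.77% and 8.80% fibroblast RNA.

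CDK4, the cyclin D-dependent kinase named in the series title, was far more abundant in HCC827 cells than in fibroblasts. HCC827 monocultures held 5904 ± 1318, 5350 ± 365 and 5323 ± 312 TPM in the NF, TAF and TCF sets, against 270.1 ± 89.8, 252 ± 10.4 and 127 ± 45.1 TPM in fibroblast monocultures (ratios 21.9, 21.2 and 42.0). In co-cultured fibroblast fractions CDK4 was at 1569 ± 1289, 2063 ± 619 and 2473 ± 897 TPM. The log2 changes were 2.27, 2.99 and 4.28 (SE 0.46 each, n = 3; limma adjusted p = 0.00918, 6.06e-04 and 1.94e-05). A mixture of both monocultures at the measured HCC827 share gave 1466 ± 1189, 2081 ± 929 and 2345 ± 822 TPM. Observed CDK4 lay at a log2 ratio to that mixture of 0.09 ± 0.03 (SD, n = 3) in NF, 0.03 ± 0.26 in TAF and 0.08 ± 0.08 in TCF. CDK4 did not lie beyond both monocultures in any set, but that test cannot decide about the fibroblasts. With the ratios of 21.9, 21.2 and 42.0 between the monocultures, only a rise larger than these could have passed. OGT and MGEA5, the enzymes that add and remove O-GlcNAc, and the retinoblastoma gene RB1 did not pass in any fibroblast co-culture. In HCC827 cells of the TCF set GFPT2, the entry enzyme of the hexosamine pathway, rose by 1.41 ± 0.36 (adjusted p = 0.0455), but TCF monocultures held 191 ± 152 TPM of it against 20.03 ± 10.4 TPM in HCC827 monoculture. Against the mixture GFPT2 lay at 0.49 ± 0.77 (SD, n = 3) in that set, within its spread of 0. It lay at 0.41 ± 0.21 in the NF set and 0.54 ± 0.31 in the TAF set, where it did not pass limma.

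**Figure D3:**
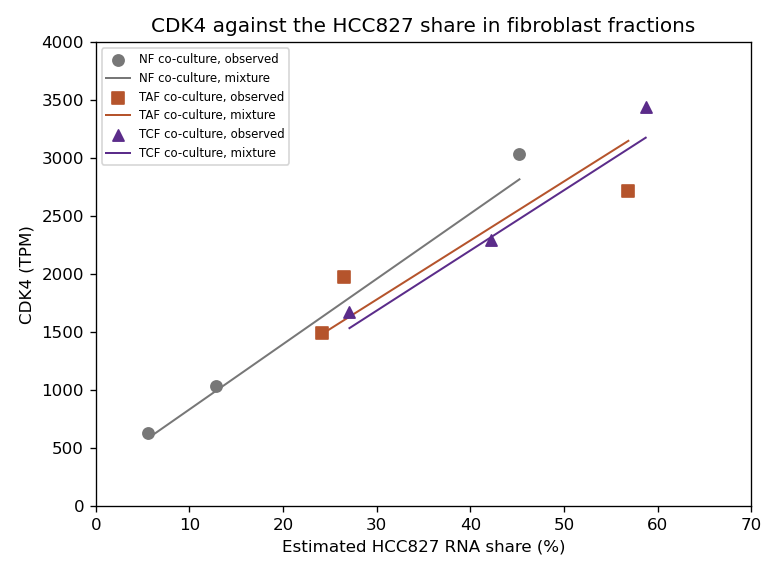
CDK4 in TPM (vertical axis) against the estimated HCC827 share of RNA in percent (horizontal axis) in the 9 co-cultured fibroblast fractions. Symbols are observed libraries and lines join the values of a mixture of the monocultures of the same set, with log2 ratios of observed to mixture averaging 0.09 (NF), 0.03 (TAF) and 0.08 (TCF).

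Among fibroblasts grown alone, TCF stood apart from the other two by low cell-cycle expression. UBE2C, a ubiquitin enzyme of mitotic exit, was at 27.8 ± 36.7 TPM in TCF, 299 ± 144 TPM in NF and 364 ± 58.3 TPM in TAF (log2 changes -4.31 ± 0.73 and -4.72 ± 0.73, n = 3; limma adjusted p = 0.00319 and 7.56e-04). TOP2A, CDC20, PLK1, CCNB2, KIF2C, ANLN and PIMREG were lower in both comparisons, with log2 changes between -4.81 and -4.07. All 23 mitosis genes were lower in TCF than in NF and than in TAF (23 in each adjusted over the list alone), with medians of -3.57 and -4.13. The camera adjusted p values were 5.49e-23 and 1.74e-19, and 0.412 and 0.301 with an estimated correlation. Of 22 S-phase genes 21 were lower than in NF and 22 than in TAF (22 in each adjusted over the list alone; camera adjusted p = 4.22e-14 and 1.46e-15, and 0.430 and 0.301 with an estimated correlation).

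IL11, a fibrogenic cytokine of the IL6 family, was higher in TCF, at 353 ± 251 TPM in TCF, 7.21 ± 4.42 TPM in NF and 18.8 ± 14.2 TPM in TAF (log2 changes 5.21 ± 0.81 and 4.02 ± 0.81; limma adjusted p = 0.00281 and 0.00371). Against NF, C11orf96, the histone genes HIST2H2AA4 and HIST1H2BC, the cytokine gene LIF, the nuclear receptor gene NR4A1, INHBA (a subunit of activin A), the protease gene ADAMTS4, FOLR3 and IER3 were also higher, by log2 changes between 2.52 and 3.54. Against TAF, POSTN (periostin) was higher by 5.54 ± 1.58, and the prostaglandin synthesis genes PTGS2 and PTGES were 19.0-fold and 18.9-fold higher. Inflammatory genes passed for 2 of 23 against NF and 6 against TAF (7 in each adjusted over the list alone), and hypoxia genes for 2 of 15 and 4 (7 and 6 adjusted over the list alone). The camera adjusted p values of the inflammatory list were 1.08e-11 and 1.86e-08, and 0.412 and 0.301 with an estimated correlation. For the hypoxia list they were 2.26e-05 and 9.28e-06, and 0.430 and 0.301 with an estimated correlation.

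In all, 1125 genes passed between TCF and NF, 124 higher and 1001 lower, and 2339 between TCF and TAF, 397 higher and 1942 lower. Upper-quartile rescaling moved the median gene by 0.146 and 0.184 and gave 193 higher and 553 lower, and 674 higher and 1160 lower. With the compared libraries alone 1 and 0 genes passed (2577 and 3533 at an unadjusted p under 0.05), and none of the genes named for either comparison did (lowest adjusted p = 0.157 and 0.0501). Against NF, 2389, 389 and 287 genes passed without TCF monoculture replicate 1, 2 and 3, and 275 and 675 without NF monoculture replicate 1 and 3. Against TAF, 1275 and 1135 passed without TCF monoculture replicate 2 and 3, and 1367 and 1226 without TAF monoculture replicate 2 and 3. Of the 20 genes named for each comparison, between 11 and 20 passed without any 1 library, with LIF, C11orf96, FOLR3, IER3 and INHBA failing most often against NF and POSTN, CEMIP, PTGS2 and PTGES among those against TAF. TAF and NF monocultures differed by 0 genes in limma, with 286 at an unadjusted p under 0.05, and limma without a trend gave 0 and 281. There camera called 12 lists, 0 of them with an estimated correlation.

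**Figure D4:**
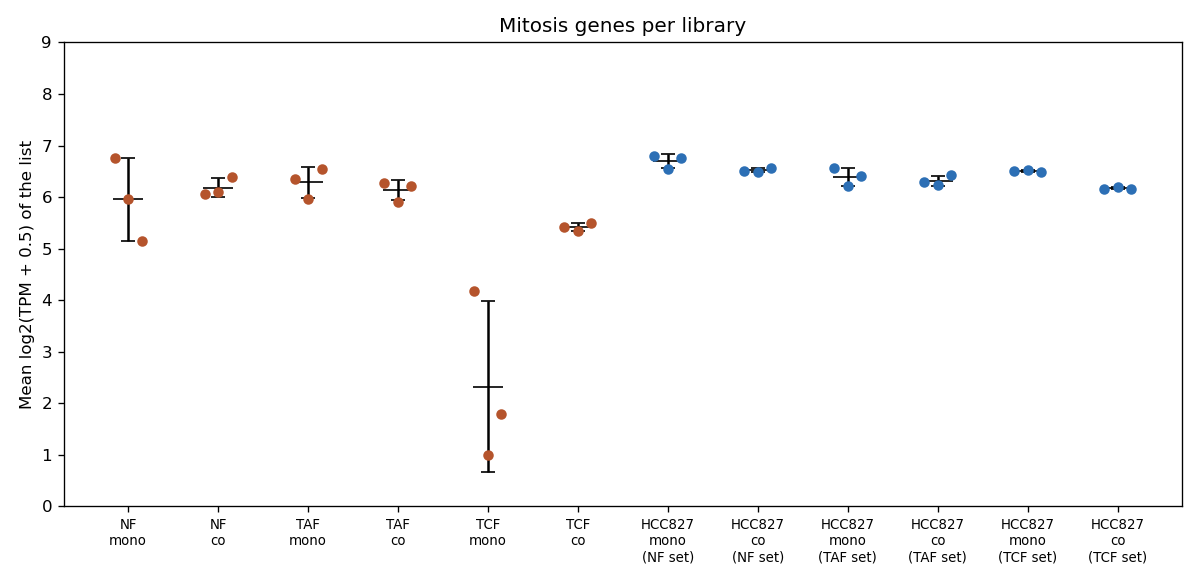
Mean log2(TPM + 0.5) of the mitosis list per library (vertical axis) in the 12 groups, fibroblast groups in orange and HCC827 groups in blue. Points are libraries, horizontal marks are means and error bars are SD (n = 3); TCF monocultures averaged 2.32, against 5.96 in NF and 6.28 in TAF monocultures.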

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

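The tests weighed in this part were chosen after the results were seen.

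The difference between groups that passed with an estimated correlation was in the lung fibroblast position transcription factors, whose co-culture response was lower in TCF than in TAF (median difference -0.53, camera adjusted p = 2.41e-06, adjusted p = 0.0195 with an estimated correlation, 0.0225 after subtraction of the other cell type with the preset correlation). By fry the adjusted p was 0.249, with the replicate block and an estimated correlation it was 0.411, and 0 of 18 genes passed by themselves. Of 186 list tests of differences between responses 57 passed camera, 1 did with an estimated correlation and 0 did by fry. Against the mixture of both monocultures the list lay at a log2 ratio of -0.38 ± 0.09 (SD, n = 3) in TCF fractions and 0.03 ± 0.13 in TAF fractions. Beyond this allowance for HCC827 RNA no explanation was tested.

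CDK4 was higher in co-cultured fibroblast fractions. RNA of HCC827 cells left in the fractions is a possible explanation: over the 9 fractions observed CDK4 lay at a mean log2 ratio of 0.0667 ± 0.138 (SD) to the mixture, within its spread of 0. In NF alone the ratio was 0.09 ± 0.03, above its spread of 0. That mixture took HCC827 levels from monocultures. Co-cultured HCC827 fractions held less CDK4, at 4802 ± 1203, 4568 ± 742 and 4393 ± 602 TPM in the NF, TAF and TCF sets. These differences did not pass limma. A mixture with these lower levels at the same share would lie lower and was not computed. The ratios therefore do not decide whether HCC827 RNA accounts for all of the CDK4. Higher CDK4 in the fibroblasts themselves stays open: after subtraction the SE of the log2 change was 1.81 in each set and the lowest adjusted p was 0.897, and the unmixed change was 0.70 ± 0.24 (SD, n = 3) in NF, -1.94 ± 6.10 in TAF and -0.47 ± 6.61 in TCF. The means of TAF and TCF are no estimate of a fall. Each holds 1 pair whose unmixed CDK4 was set to 0, TAF replicate 1 (-8.98) and TCF replicate 2 (-7.99). The other pairs gave 1.76 and 1.39 in TAF, and 2.21 and 4.38 in TCF. Protein or its modification was not measured here.

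Part of the interferon-stimulated genes lay above both monocultures in co-cultured fibroblast fractions: most of the list in NF, but a minority in TAF and TCF. In TAF and TCF the calls above both were lost without certain single libraries. The tables argue against RNA of HCC827 cells left in the fractions as the whole cause: even against a mixture with the HCC827 fractions of the same co-cultures, the list lay higher by a mean log2 ratio of 1.87 ± 1.16 (SD, 9 fractions). A response of the fibroblasts larger than that of HCC827 cells is consistent with the unmixed values, where the fibroblast change exceeded the HCC827 change in 9 of 9 pairs, by 3.46 ± 0.719 on the log2 scale, from a lower level in monoculture. This is a larger fold rather than a higher level throughout, as between 9 and 18 of the 21 genes were higher in the fibroblasts, and the pairs of the TCF set are uncertain, since their replicate numbers did not pair the fractions. Stress of separation, a step stated only for co-cultures, cannot be told apart from co-culture by the design, and heat shock genes lay at a mean log2 ratio of -0.0565 ± 0.173 to the mixture. The lower number of cells plated per cell type in co-cultures cannot be told apart from co-culture either.

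Cell-cycle genes were lower in TCF monocultures than in NF and TAF monocultures. The tables argue against 1 aberrant TCF library, since 3 of 3 TCF libraries lay below all 6 NF and TAF libraries (TCF from 1.00 to 4.18, lowest of the others 5.15, as mean log2 of the mitosis list). TCF replicate 1 stood apart from the other two, and in the S-phase list it lay at 5.08, near the lowest NF library at 5.32. They argue against the scaling of the TPM values, since the median change nearer 0 was -3.43 with upper-quartile rescaling. Tissue region and the dissociation kit cannot be told apart, because only tumour-core tissue was dissociated with its kit, and the calls were lost with the compared libraries alone.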

How the results depend on the processing

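All alternatives were planned except leaving out the co-culture library with the largest share of the other cell type; leaving out single libraries is given beside each result above. Of 180 comparisons of a count, share or list total with an alternative other than these single libraries, 138 stayed within 1.5 times (shares within their SD) and 42 did not. A main count of 0 that stayed 0 is among the 138, so they overstate how stable the counts above 0 were. Such counts were those of the response differences, TAF against NF, HCC827 monocultures between sets, and HCC827 beyond both in the TAF and TCF sets. Of 1008 comparisons for named genes, 898 kept direction and call, 110 kept direction only, and 0 reversed; genes named for NF, TAF and TCF co-cultures kept their call against their own monoculture throughout, but not always beyond both. Depth is unknown, and simulated recovery at a fold of 2 was limited, with no other group size than 3 simulated. With the compared libraries alone, which leaves fewer libraries for the variance, counts were 167 (NF), 1260 (TAF) and 1426 (TCF) for co-cultures, 39 and 75 for HCC827 in the NF and TAF sets, 0 and 6 beyond both for TAF and TCF, and 1 and 0 for TCF against NF and TAF. With the replicate block they were 1111, 2057 and 4790 for NF, TAF and TCF, and 762 and 72 for HCC827 in the NF and TAF sets. After subtraction of the other cell type they were 75, 34 and 91, and 37, 0 and 0 for HCC827, counts that a wider spread after subtraction can also lower. With all 9 HCC827 monocultures as control they were 1568, 276 and 1421. Without a filter they were 151 and 29 for HCC827 in the NF and TAF sets, and beyond both 12 in the NF set and 1 in the TCF set. HCC827 in the TAF set gave 29 without trend and 152 with a pseudocount of 0.1. Upper-quartile rescaling gave 746 for TCF against NF and 1 beyond both for HCC827 in the TCF set. Without the library of largest other-cell share they were 258 for NF, 433 for TAF, 126 and 5 for HCC827 in the NF and TAF sets, 0 beyond both for TAF and for HCC827 in the NF set, 3 for HCC827 in the TCF set, and 2 for the TAF against NF response. List calls numbered 168, against 15 with an estimated correlation and 54 by fry. In co-culture comparisons they numbered 126, against 77 after subtraction, some of them new. Leaving out 1 library gave between 216 and 634 for NF, 433 and 768 for TAF and 1864 and 3178 for TCF co-cultures, and for HCC827 between 25 and 1046, 5 and 93, and 148 and 326 in the NF, TAF and TCF sets. Beyond both it gave between 48 and 82 for NF, 0 and 15 for TAF, 0 and 19 for TCF, and 0 and 32 for HCC827 in the NF set. For TCF monocultures it gave between 275 and 2389 against NF and 1135 and 3270 against TAF, and for responses up to 352 (TCF against NF) and 369 (TCF against TAF). Beyond these constructions the cause was not tested.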

Other observations

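The tests of this part were chosen or labelled after the results were seen.

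SOD2 in fibroblast fractions lay above the mixture of both monocultures, by a log2 ratio of 2.34 ± 0.47 (SD, n = 3) in NF, 1.36 ± 0.29 in TAF and 1.95 ± 0.09 in TCF. IL6 lay at 2.89 ± 0.48, 1.70 ± 1.14 and 1.68 ± 0.90, and CXCL8 at 3.60 ± 0.87 in NF, 2.83 in TAF (lowest library 1.49) and 1.80 ± 2.38 in TCF, the last within its spread of 0. The inflammatory list lay at 1.38 ± 0.27 in NF, 0.71 ± 0.42 in TAF and 0.64 ± 1.06 in TCF, again within its spread of 0 in TCF. NRF2 target genes lay below the mixture in NF (-0.48 ± 0.17) and TAF (-0.26 ± 0.07), and within their spread of 0 in TCF (-0.07 ± 0.07).

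Other splits of the same libraries were counted for each test over all genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For co-culture against monoculture, 1 of the 10 splits, the real one, gave as many genes in each of the 6 comparisons: 452 in NF (highest other 0), 816 in TAF (1), 2811 in TCF (323), and for HCC827 cells 281 in the NF set (0), 46 in the TAF set (0) and 383 in the TCF set (7). The split of TCF with 323 kept a pair with the same replicate number together, and splits that part all pairs, as the real one does, gave at most 0.

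Beyond both monocultures, 2 splits, the real one included, gave as many as the real 74 in NF (highest other 114), 2 as many as the real 7 in TAF (7), 5 as many as the real 22 in TCF (1220), and 1 as many as the real 20 for HCC827 in the NF set (6). Each other split was counted under both labellings and the larger count kept, the real one only as labelled. The monocultures of the other cell type were not exchanged. These counts are therefore no even reference for the real ones and decide nothing. For HCC827 in the TAF and TCF sets all 10 splits necessarily gave as many as the real 0 (highest other 1 and 0). The 114, 7 and 1220 genes came from splits that kept a pair with the same replicate number together, and splits that part all pairs, as the real one does, gave at most 0 in NF, TAF and TCF. The 1220 genes, many times the real count, may come from this way of counting or from a structure of the samples, and the cause was not tested. For TAF against NF all 10 splits gave as many as the real 0 (highest other 1), for TCF against NF 1 split gave as many as the real 1125 (0) and for TCF against TAF 1 split gave as many as the real 2339 (1).

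For differences between responses 100 splits were drawn, and all 100 gave as many genes as the real 0, which a count of 0 makes certain, so these splits decide nothing. The highest other counts were 6 for TAF against NF, 1221 for TCF against NF and 1459 for TCF against TAF, and for HCC827 cells 1488, 41 and 9 in the same order. The highest of these counts may come from a structure of the samples, which was not tested. For HCC827 monocultures between sets all 100 splits gave as many as the real 0, with 0 the highest other.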
